A study of Mus musculus with 6 samples.

How the data were processed

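Peripheral blood mononuclear cells of 6 libraries were analysed, 3 from the saline-injected control group (Con) and 3 from the streptozotocin-injected diabetic group (T2D), with groups and library numbers taken from the sample titles. Per the labels' protocols, blood cells were isolated by density centrifugation and lysis of red blood cells, and whole-transcriptome libraries were made from the 3′ end of messenger RNA with the BD Rhapsody system, in which each molecule carries a cell label and a UMI. The labels give no batch. The submitters' processing notes name CASAVA 1.8, UMI-tools, Seurat and the genome build mm10, without roles or settings, and the aligner and gene annotation version are not given in the sources used here. The deposited values are raw UMI counts per gene and cell barcode, 1 matrix per library, as the authors made them: whole numbers with totals that differ between libraries, and a lowest barcode total of 501 to 503 UMIs in each library. The matrices hold 31253 genes with their identifiers and symbols, and 43 symbols are shared by more than 1 gene. Of the identifiers, 31107 matched a reference table of gene names and 30203 of those had the same symbol. Gene coordinates were not used here. No strand setting of the counting is given, so UMIs of overlapping or antisense genes, and of near-identical copies, may be assigned to either.

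All computations started from the counts. Libraries were checked for duplicates by a chi-square comparison of their gene totals, and all pairs differed by more than sampling noise (chi-square over degrees of freedom 8.89 at the lowest). Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept, 49025 of 49407. The median mitochondrial share per library was 4.31% to 5.39%. Doublets were scored per library by an own implementation of the scheme of scrublet (simulated doublets, expected rate 0.06). A single score threshold of 0.2688, the median of the 6 libraries' own thresholds, was used for all libraries, which was decided after those thresholds had been seen, and 1529 cells (2.75% to 3.41% of a library) were left out. Doublets of 2 cells of the same type and those with a small second cell escape such scores.

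The 47496 remaining cells were clustered together with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9: log-normalised counts, 2000 variable genes, 30 principal components, 20 neighbours, a shared-neighbour graph and Leiden clustering at resolution 1 with seed 0. V(D)J segments, mitochondrial, ribosomal protein and haemoglobin genes were left out of the variable genes. The pattern for V(D)J segments at first also removed Ighd and was corrected after the first clustering. Clusters were named from 22 marker lists fixed before the data were examined, and the scoring of markers was set while looking at the clusters: a pseudocount of 20 CPM for folds, a marker detected in at least 0.1 of the cells, at least 3 markers detected, a mean marker score of at least 0.8 and a margin of 0.25 to the next class. Clusters that failed stayed unnamed and were kept by number when they held at least 100 cells. The eosinophil-like class rests on only 3 detected markers. Numbered clusters of low UMI content, or led by platelet or interferon-stimulated genes, were not tested for gene changes, a rule made after the clusters had been seen. These were Cluster 8 (1.96% of Con and 3.19% of T2D cells), Cluster 17 (low-UMI monocyte-like, 1.15% and 1.33%), Cluster 20 (platelet genes, 0.667% and 0.775%), and Cluster 21 (interferon-stimulated genes, 0.571% and 0.718%). Cluster 22 had too few cells in some libraries to be tested. The rule on low UMI content did not cover named classes, such as eosinophil-like and platelet-like cells with medians of 948 and 825 UMIs. Other small unnamed clusters together made up 0.220% and 0.317%. Whether the classes whose share passed depend on their leading genes was checked by clustering again without 58 of these genes, a check added after the result was seen. Cluster 10 then held 1.15% of Con and 4.47% of T2D cells, regulatory T-like cells 0.746% and 2.61%, NK-like cells 1.77% and 3.03%, Cluster 22 0.165% and 0.598% and Cluster 8 2.23% and 3.60%, while no new cluster matched the gamma-delta T-like class, so that share stays uncertain.

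The library was the unit of every test, since cells are not replicates. Cells per class were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with the kept cells of a library as its size and Benjamini-Hochberg adjustment over the classes, beside a two-sided exact permutation test over the 10 splits of the libraries. For gene expression, counts were summed per library and class where every library had at least 30 cells of the class, which left 12 classes and clusters, and tested with edgeR's robust quasi-likelihood test (TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). The same test was run on all kept cells of a library summed. Per library, the sums ranged from 43 to 150 cells for eosinophil-like to 3461 to 4808 for B-like cells. The 35 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on lists with at least 5 tested members, adjusted over all lists and classes. Of 887 list genes, 4 had no gene of that name in the matrices. Differences of the T2D effect between the 4 largest tested classes were tested by an interaction term in edgeR with the library as a block.

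Genes were named by a rule fixed before the data were examined: among genes with adjusted p under 0.05, at least 20 CPM and no overlap between groups, the 10 with the largest rise and the 10 with the largest fall in each of the 4 tested classes with the most cells, 4 and 4 in each other class and 5 and 5 in all cells. Up to 4 members of a list were named by smallest p, and only in classes where the list passed, which was decided after the results had been seen. V(D)J segments, mitochondrial, haemoglobin, Y-linked and ribosomal protein genes, Xist and unnamed gene models were counted but not ranked. A few leading genes of clusters and changed genes are not reported here. From these, the text prefers genes whose call held without each library in turn.

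The tests were checked on simulated counts drawn from the real means and library sizes, with 200 genes changed. In the B-like simulation (11460 genes), 46 of 67 tested genes changed by 1.5-fold, 56 of 64 changed by 2-fold and 63 of 63 changed by 4-fold were called, with 10 false calls. In the NK-like simulation (6637 genes) these were 22 of 65, 52 of 63 and 59 of 60, with 8 false calls, and in the neutrophil-like simulation (4136 genes) 13 of 61, 38 of 63 and 60 of 62, with 7. The interaction test of CD8 T-like against B-like cells (9742 genes) called 31 of 66, 52 of 66 and 62 of 65, with 9 false calls. A doubled NK-like share was called in 8 of 20 simulations, with 4 calls of other classes.

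Alternatives listed before the data were examined were size factors by median of ratios, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 10 counts, the replicate number as a block, each library left out, doublets kept, at most 10% mitochondrial UMIs with at least 500 genes, resolutions 0.5 and 2, equal cell numbers per library, an estimated correlation and fry for the lists, and for shares TMM scaling, named leukocytes as denominator and limma on log2 odds. pandas 2.3.3, scikit-image 0.26.0 and matplotlib 3.10.9 were used for tables, thresholds and plots.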

Results

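Single-cell transcriptomes of peripheral blood mononuclear cells were compared between male mice of 12 to 13 weeks with streptozotocin-induced type 2 diabetes (T2D) and control mice injected with saline (Con). The series title gives the model as high-fat diet with streptozotocin, which is a toxin taken up by insulin-producing beta cells. Each group held 3 libraries, made with a bead-and-microwell system that counts messenger RNA molecules by unique molecular identifiers (UMIs). The count matrices held 7404 to 9112 cell barcodes per library and 25580045, 23574052 and 27157764 UMIs in Con 1, 2 and 3, against 29329361, 32321855 and 29712873 in T2D 1, 2 and 3. After filtering, 47496 cells remained (7109 to 8702 per library), with a median of 2774 to 3189 UMIs and 1381 to 1576 genes per cell. The labels do not say whether a library came from 1 mouse or a pool, so p-values measure only the spread between these libraries, which may be partly technical. The diet of the control mice is not given in the sources used here.

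The cells fell into 33 clusters, of which those whose markers allowed it were called X-like. B-like cells were led in separate clusters by Fcer2a, H2-Eb1 and Cd83 (Cluster 0), Cr2 and Bank1 (Cluster 1), Vpreb3 and Cecr2 (Cluster 4), Fchsd2 and Ighd (Cluster 5), Bhlhe41 and Fcrl5 (Cluster 7), and Ifit3 and Slfn5 (Cluster 12, interferon-stimulated genes). CD4 T-like cells were led by Cd4, Igfbp4 and Lef1, CD8 T-like cells by Cd8b1 with Itgae or Ly6c2, regulatory T-like cells by genes that include Ctla4, Icos and Ikzf2, and NK-like cells by Ncr1, Klrb1c and Gzma. Foxp3 and Il2ra were not among the leading genes of the regulatory T-like class. Its marker score was 2.37, with CD4 T cells next at 2.02. Classical monocyte-like cells were led by Ccr2, Lyz2 and F13a1, non-classical monocyte-like cells by Ace, Ear2 and Adgre4, neutrophil-like cells by Cxcr2, Csf3r and Il1b, and eosinophil-like cells by Ccr3 and Alox15. Cluster 10 stayed unnamed and was led by Ccl5, Klrc1, Gzmk, Nkg7 and Klrg1, genes of effector and memory T cells and NK cells. Cluster 16 was led by Trdc, Trgc1, Trgc2 and Il2rb, and Cluster 22 by Igha, Jchain and Mki67, which mark antibody-secreting and dividing cells. Cluster 8 held cells with a median of 780 UMIs and was led by Txk, a kinase of T cell receptor signalling.

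**Figure D1:**
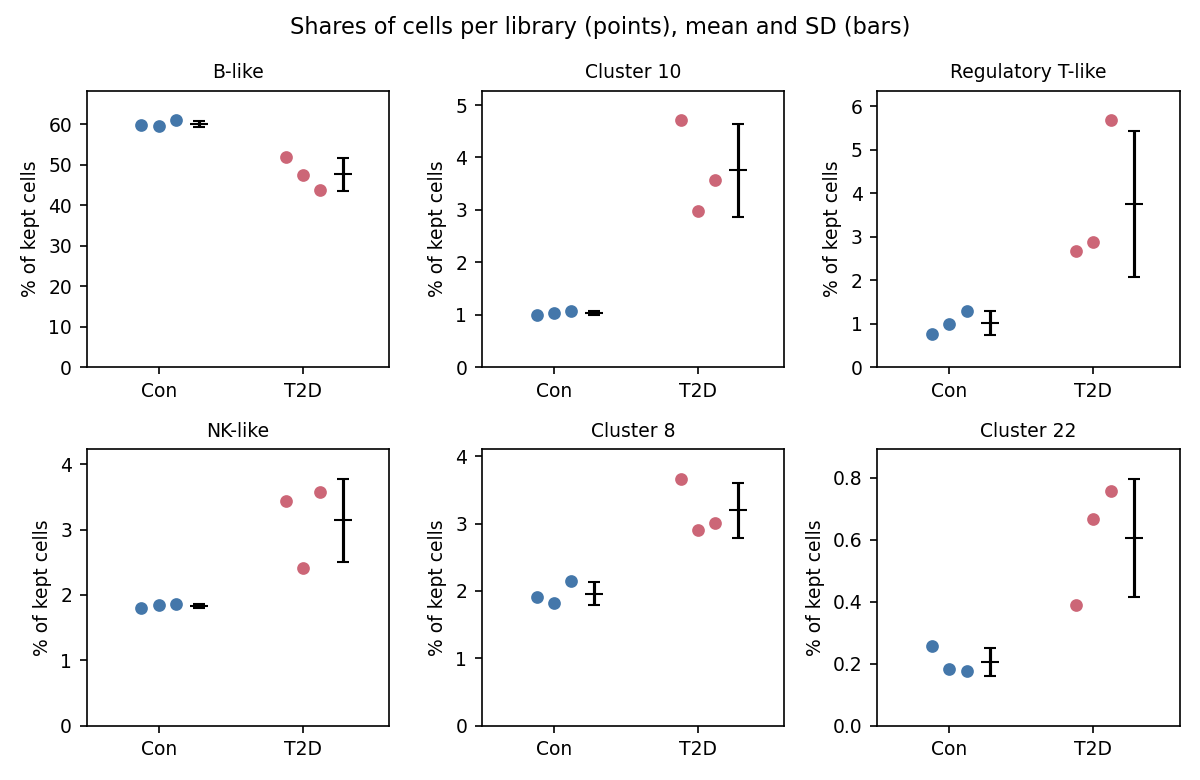
Share of each library's kept cells (%, y axis) that fell in 6 classes or clusters, by group (x axis), with 1 point per library, the mean and the SD. B-like cells went from a mean of 60.1% in Con to 47.7% in T2D, Cluster 10 from 1.04% to 3.75%, regulatory T-like cells from 1.01% to 3.75%, NK-like cells from 1.84% to 3.14%, Cluster 8 from 1.96% to 3.19% and Cluster 22 from 0.206% to 0.606%.

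The first comparison asked whether the makeup of the blood cells differed between T2D and Con. Cluster 10, led by cytotoxic and memory lymphocyte genes, rose from 1.04% ± 0.037 (SD, n = 3) of cells in Con to 3.75% ± 0.88 in T2D. Its log2 fold change was 1.85 ± 0.24 (SE; adjusted p = 0.00251, edgeR quasi-likelihood). Regulatory T-like cells rose from 1.01% ± 0.27 to 3.75% ± 1.68 (1.88 ± 0.38, adjusted p = 0.014). Of the 1156 cells in that class, 761 stayed together when clusters were made again without leading genes. Cluster 22, led by immunoglobulin genes of antibody-secreting cells, rose from 0.206% ± 0.045 to 0.606% ± 0.19 (1.55 ± 0.33, adjusted p = 0.0150). NK-like cells, innate cytotoxic lymphocytes, rose from 1.84% ± 0.030 to 3.14% ± 0.64 (0.77 ± 0.22) and the low-UMI Cluster 8 from 1.96% ± 0.17 to 3.19% ± 0.41 (0.71 ± 0.20), both with adjusted p = 0.0369. The small gamma-delta T-like class of 48 cells rose from 0.0491% ± 0.0062 to 0.147% ± 0.026 (1.55 ± 0.31, adjusted p = 0.014), and had no match when clusters were made again without leading genes.

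These 6 of the tested shares passed the threshold, and all were higher in 3 of 3 T2D libraries than in every Con library. Each gave p = 0.1 in a two-sided exact permutation test, the smallest that 3 libraries against 3 allow. The B-like share, 60.1% ± 0.81 in Con and 47.7% ± 4.08 in T2D, gave a log2 fold change of −0.33 ± 0.18 with no overlap between groups and did not pass (adjusted p = 0.224, exact permutation p = 0.1), while TMM scaling over class counts gave −0.65 (adjusted p = 0.0359). Shares of a library add up to a fixed total, so a lower B-like share would by itself raise the other shares, the 6 above among them. Absolute cell numbers were not used here. Within the B-like class, Cluster 0 held 41.4% ± 2.65 (SD, n = 3) in Con and 33.9% ± 5.57 in T2D, and Cluster 1 held 25.9% ± 1.42 and 35.1% ± 6.10. Eosinophil-like cells made up 1.33% of Con and 0.604% of T2D cells (adjusted p = 0.0559) and Cluster 16 made up 0.975% and 1.6% (adjusted p = 0.0715). CD8 T-like (10.5% and 12.6%), CD4 T-like (9.91% and 11.5%), neutrophil-like (2.29% and 2.03%) and classical monocyte-like cells (2.10% and 1.93%) did not pass either. The NK-like share lost its call without Con 1, Con 2, Con 3, T2D 1 or T2D 3 (adjusted p 0.113, 0.108, 0.0851, 0.114 and 0.104), and so did Cluster 8 (0.113, 0.115, 0.0693, 0.112 and 0.0809). Both also lost it with the library number as a block (0.0810 for NK-like cells and 0.0867 for Cluster 8), with limma on log2 odds (0.0533 each) and with TMM scaling (0.46, adjusted p = 0.194, and 0.40, adjusted p = 0.2095). The gamma-delta T-like share lost its call with doublets kept (0.75, adjusted p = 0.0618). Cluster 22 lost its call without Con 3 or T2D 3 (0.0551 and 0.0511), eosinophil-like cells passed without Con 2 (adjusted p = 0.0471), with TMM scaling (−1.47, 0.0359), with the block (0.0485) and at resolution 0.5 (0.0495), and Cluster 16 without Con 3 (0.0484), and 3 shares passed without T2D 3.

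The second comparison asked which genes differed in expression between T2D and Con within each class, on UMIs summed per library and class, in CPM, the UMIs of a gene scaled to a fixed total per class sum. Nr4a3 fell in CD4 and CD8 T-like cells and Nr4a1 in regulatory T-like cells, 2 orphan nuclear receptors induced by antigen receptor signals. Of the genes of AP-1 subunits, Junb fell in B-like, CD4 T-like and NK-like cells and in Cluster 10, Fosb in CD4 T-like and Fosl2 in CD8 T-like cells, while Fos rose in Cluster 16. Interferon-stimulated genes that rose included Iigp1 in CD4 T-like, Igtp in CD8 T-like and Ifit3b in neutrophil-like cells. H1f2, H1f3 and H1f4, each for a linker histone, rose in NK-like cells, and H1f2 and H1f4 in classical monocyte-like cells. Nfkbie, an inhibitor of NF-kB, fell in neutrophil-like cells, and in classical monocyte-like cells the NF-kB subunit gene Rel fell while the chemokine gene Ccl2 rose. Within the classes, a gene or list given without a left-out library kept its call in each of the 6 fits without 1 library. This does not cover values set side by side for a difference of the T2D effect between classes. All adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

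**Figure D2:**
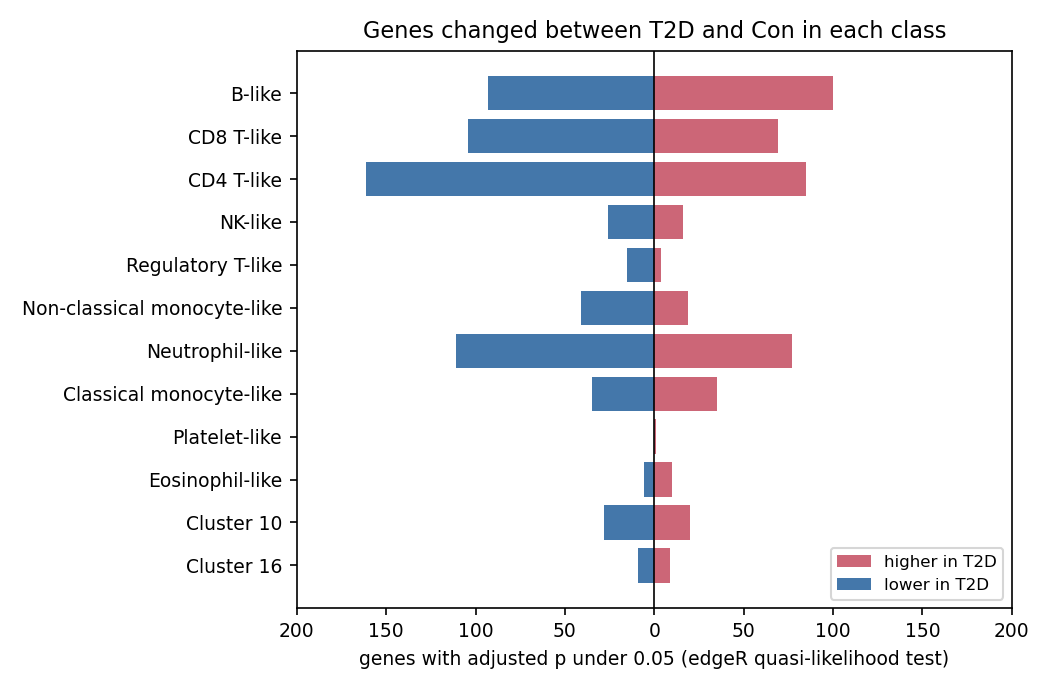
Number of genes (x axis) higher or lower in T2D than in Con at adjusted p under 0.05 in each class (y axis), with bars to either side of 0. B-like cells had 100 higher and 93 lower genes, CD8 T-like 69 and 104, CD4 T-like 85 and 161, and neutrophil-like 77 and 111.

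In B-like cells, Junb fell from 1755 ± 112 CPM (SD, n = 3) in Con to 1048 ± 122 in T2D (log2 fold change −0.74 ± 0.08, SE; adjusted p = 0.000172). The kinase gene Pim3 fell from 146 to 88.3 CPM (−0.73 ± 0.06, adjusted p = 7.36e-06). Cdkn1a, the cell cycle inhibitor p21, fell from 30.3 to 11.2 CPM (−1.44 ± 0.14, adjusted p = 0.000216). Phf13 (−0.73), Sertad3 (−0.68), Klf16 (−0.64), Snhg15 (−0.62), Midn (−0.57) and the cyclin-dependent kinase inhibitor gene Cdkn2d (−0.55) also fell. Cpt1a, which controls fatty acid import into mitochondria, rose from 159 to 238 CPM (0.58 ± 0.08, adjusted p = 0.00224). Ccl5, a chemokine of T and NK cells, rose from 26.9 to 60.2 CPM (1.16 ± 0.14, adjusted p = 0.00513). Hilpda, a lipid droplet gene (0.57), rose but lost its call without Con 1 or Con 2 (highest adjusted p 0.0697). The T cell factor gene Tcf7 (0.55) lost its call without Con 1, Con 2 or T2D 3 (0.101) and Il7r (0.77) without Con 1, T2D 1 or T2D 3 (0.129). T cell transcripts as a list rose in the same cells (median 0.43; adjusted p = 0.516 with an estimated correlation). Without Con 2, Spn (0.59; 0.0879) and Gvin1 (0.60; 0.0905) lost it. The Notch target gene Hes1 fell (−1.23) and lost its call without Con 1, Con 2 or T2D 3 (0.139). In all, 193 of 11576 tested genes changed (100 higher, 93 lower) and 20.4% of genes had no overlap between groups, where chance gives 10% on average over the 10 splits. Genes move together, so a single split can lie above or below that average. The share was not computed for the other splits, here or in the classes below. The count of changed genes was 89 without Con 1, 43 without Con 2, 297 without T2D 1 and 126 without T2D 3, and 11 of the 20 genes named by the rule kept their call throughout.

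In CD8 T-like cells, Nr4a3 fell from 37.5 to 14.0 CPM (−1.41 ± 0.16, adjusted p = 4.48e-06) and Rgs1, a brake on chemokine receptor signalling, from 251 to 138.5 CPM (−0.86 ± 0.08, adjusted p = 3.91e-06). Plaur, the urokinase receptor gene (−1.14), Fosl2, an AP-1 subunit (−0.81), Nfkbid, a regulator of NF-kB (−0.74), Gch1, of tetrahydrobiopterin synthesis (−0.72), and Sit1, an adaptor that dampens T cell receptor signals (−0.70), fell with Phf13 (−0.91) and Klf16 (−0.82). Ly6a, an interferon-inducible surface protein gene, rose from 80.6 to 136 CPM (0.75 ± 0.08, adjusted p = 8.93e-07) and the transcription factor gene Myb from 60.0 to 99.1 CPM (0.73 ± 0.10, adjusted p = 6.11e-05). The Notch-modifying gene Lfng rose from 116 to 175 CPM (0.60) and Igtp, an interferon-inducible GTPase gene, from 81.6 to 122 CPM (0.57). Tmie (0.91), Clec2d (0.57) and Zfp281 (0.57) rose too. Smad7, an inhibitor of TGF-beta signalling, fell (−0.76) but lost its call without T2D 3 (0.0582). Of 10014 genes 173 changed (69 higher, 104 lower), 18.6% without overlap against 10% by chance. There were 88 without Con 1, 81 without Con 2 and 114 without Con 3.

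In CD4 T-like cells 246 of 9504 genes changed (85 higher, 161 lower), with 19.4% without overlap against 10% by chance. Nr4a3 fell from 126 ± 14.2 to 27.9 ± 8.31 CPM (−2.20 ± 0.16, adjusted p = 5.30e-06) and the circadian repressor gene Per1 from 542.5 to 286 CPM (−0.93 ± 0.07, adjusted p = 2.26e-10). The AP-1 gene Fosb (−1.34), Klf16 (−1.11), Nfkbid (−1.10), Plaur (−1.03), Csrnp1 (−0.98), Sit1 (−0.87) and the transcriptional repressor gene Erf (−0.85) also fell. Iigp1, an interferon-inducible GTPase gene, rose from 35.5 to 71.2 CPM (1.00 ± 0.14, adjusted p = 9.87e-05). Ccl5 rose from 24.8 to 52.9 CPM (1.06, adjusted p = 0.000311), with Neb (1.26), Tmie (1.22), the kinase gene Hipk2 (0.80) and Syt11 (0.74). Ccl5 also led Cluster 10, whose share rose, and had 1.16 in B-like cells. The source of its UMIs was not tested. The count was 128 without Con 2, 156 without T2D 1 and 147 without T2D 3.

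In NK-like cells, H1f2 rose from 165 ± 18.4 to 398 ± 47.4 CPM (1.26 ± 0.13, adjusted p = 6.15e-09). H1f3 rose from 11.8 to 60.8 CPM (2.29 ± 0.37) and H1f4 from 81.9 to 160 CPM (0.95, adjusted p = 0.00111), while H1f0, the fourth linker histone gene tested there, had 0.39 (adjusted p = 0.902). Tcf7, a transcription factor of less mature NK and T cells, fell from 240 to 128 CPM (−0.88, adjusted p = 0.000746). Transcripts that B cells make in abundance fell in the same cells, H2-Aa from 373 to 186 CPM (−1.0, adjusted p = 2.89e-07), H2-Eb1 from 270 to 131 CPM (−1.03) and Ighm from 471 to 253 CPM (−0.90, adjusted p = 1.85e-06). Cx3cr1, a chemokine receptor gene of mature NK cells, rose from 192 to 324 CPM (0.74) but lost its call without T2D 2 (0.103). Of 6837 genes 42 changed (16 higher, 26 lower; 26 without Con 2), 13.7% without overlap against 10% by chance, from 131 to 299 cells per library.

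In regulatory T-like cells, Nr4a1 fell from 475 to 213.5 CPM (−1.13 ± 0.15, adjusted p = 7.47e-06) and Smad7 from 365 to 173 CPM (−1.06 ± 0.14). Cxcr3, a chemokine receptor gene of type 1 responses, rose from 121 to 241 CPM (0.96 ± 0.18, adjusted p = 0.00475) and lost its call without Con 3 (0.0518). Lfng rose (0.79) and lost its call without Con 2, Con 3 or T2D 1 (0.243). In all, 19 of 7130 genes changed (4 higher, 15 lower), 14.5% without overlap against 10% by chance, with 56 to 449 cells per library. That count was 4 without Con 2, 11 without Con 3 and 38 without T2D 3.

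**Figure D3:**
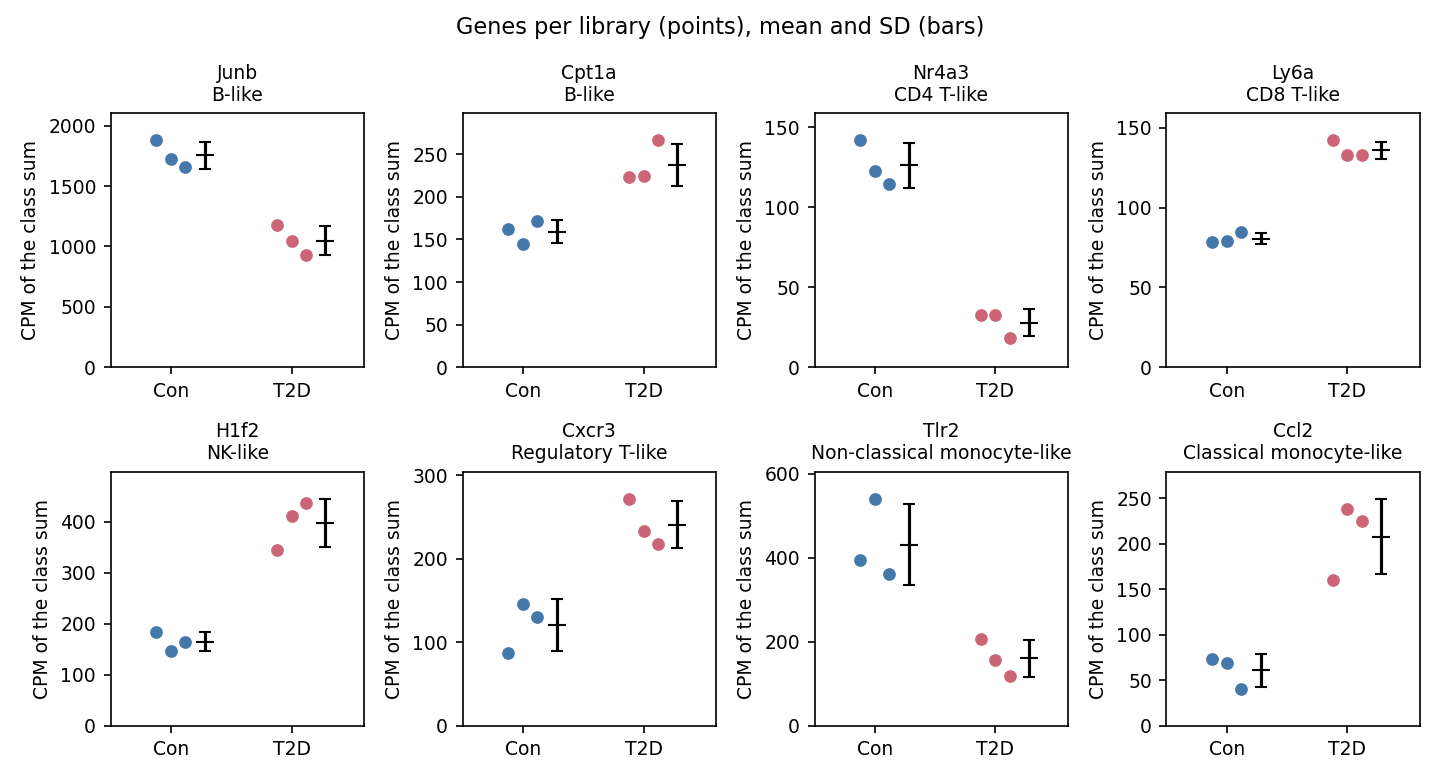
Expression of 8 genes (Junb ENSMUSG00000052837, Cpt1a ENSMUSG00000024900, Nr4a3 ENSMUSG00000028341, Ly6a ENSMUSG00000075602, H1f2 ENSMUSG00000036181, Cxcr3 ENSMUSG00000050232, Tlr2 ENSMUSG00000027995 and Ccl2 ENSMUSG00000035385; CPM of the class sum, y axis) in Con and T2D libraries (x axis), each panel 1 gene in 1 class, with 1 point per library, the mean and the SD. Group means went from 1755 to 1048 for Junb and from 159 to 238 for Cpt1a in B-like cells, from 126 to 27.9 for Nr4a3 in CD4 T-like and from 80.6 to 136 for Ly6a in CD8 T-like cells. They went from 165 to 398 for H1f2 in NK-like, from 121 to 241 for Cxcr3 in regulatory T-like, from 431.5 to 160.0 for Tlr2 in non-classical and from 60.8 to 208 for Ccl2 in classical monocyte-like cells.

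In classical monocyte-like cells, the monocyte-attracting chemokine gene Ccl2 rose from 60.8 to 208 CPM (1.75 ± 0.19, adjusted p = 0.000158) and H1f4 from 10.9 to 51.9 CPM (2.26). The NF-kB subunit gene Rel fell from 397 to 183 CPM (−1.11, adjusted p = 6.30e-07). The acute-phase gene Saa3 rose from 4.59 to 37.8 CPM (3.23) but lost its call without Con 1, Con 2 or Con 3 (0.252). In non-classical monocyte-like cells, Tlr2, a receptor for bacterial lipoproteins, fell from 431.5 to 160.0 CPM (−1.45 ± 0.19, adjusted p = 0.00115). There Fkbp5, a glucocorticoid-induced co-chaperone gene (2.06), lost its call without Con 1, Con 2 or T2D 3 (0.260). Thbs1 (1.62) lost it without Con 1 or T2D 2 (0.130), and Olr1, the oxidised LDL receptor gene (−2.07), without Con 1, T2D 1, T2D 2 or T2D 3 (0.233). Of 7979 genes 70 changed in classical cells (35 higher, 35 lower; 13.9% without overlap against 10% by chance) and 60 of 7332 in non-classical cells (19 and 41; 14.3%). The classical count was 46, 21 and 41 without Con 1, 2 and 3, 107 without T2D 1 and 38 without T2D 2. The non-classical count was 14 without Con 1, 30 without Con 2, and 99, 22 and 29 without T2D 1, 2 and 3.

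In neutrophil-like cells the stress-response gene Gadd45b fell from 796.5 to 143 CPM (−2.57 ± 0.25, adjusted p = 2.36e-05) and Nfkbie from 289 to 67.4 CPM (−2.19), an inhibitor of NF-kB, with Cdk5r1 (−2.20). The chemokine receptor gene Cxcr1 rose from 9.19 to 66.5 CPM (2.45) with Tubb2a (2.30). Ifit3b, an interferon-stimulated gene, rose from 2 UMIs over the Con libraries to 74 over the T2D libraries, a ratio of 39.2 (exact 95% interval 10.5 to 330, counting error only). Its count is uncertain because Ifit3 is a near-identical copy. Acot1, which releases fatty acids from coenzyme A, rose from 32.2 to 183 CPM (2.62) but lost its call without Con 2 (0.0665). The tissue factor gene F3 fell from 50.6 to 8.15 CPM (−2.97) and lost it without Con 2 (0.0985). Of 4360 genes 188 changed (77 higher, 111 lower; 16.9% without overlap against 10% by chance), and 73 changed without Con 2. Without T2D 3 the balance turned, with 108 higher and 83 lower.

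Eosinophil-like cells showed a fall of Rgs1 from 1805 to 561 CPM (−1.66 ± 0.24, adjusted p = 0.000232), while Il7r rose from 75.5 to 374 CPM (2.44) and lost its call without Con 1 or T2D 1 (0.166). There 16 of 1510 genes changed (10 higher, 6 lower; 16.4% without overlap against 10% by chance), with 1 without Con 1, 2 without Con 2, 9 without Con 3 and 2 without T2D 1. Without the filter on low counts the balance turned, with 5 higher and 11 lower. The class had a median of 948 UMIs per cell and sums of 51231 to 173202 UMIs per library. B cell transcripts also passed higher there as a list with the preset correlation, but not with an estimated one. The source of the Il7r UMIs was not tested. In platelet-like cells only the MHC class I gene H2-D1 changed, from 1946 to 3437 CPM (0.83 ± 0.14, adjusted p = 0.0282), of 1211 genes, of which 99 had an unadjusted p under 0.05. That gene lost its call without Con 1, Con 2, T2D 1 or T2D 2 (0.321), and 0 genes passed without Con 1, T2D 1 or T2D 2 against 2 without T2D 3. In Cluster 10, the costimulatory receptor gene Icos rose from 44.5 to 115 CPM (1.34, adjusted p = 0.00165) and Plac8 from 87.3 to 216 CPM (1.31, adjusted p = 0.000171). Trdc, the constant region of the delta T cell receptor, fell from 243 to 75.3 CPM (−1.69, adjusted p = 0.00757). The tissue-homing receptor gene Cxcr6 rose there (0.95) and lost its call without Con 1, Con 3 or T2D 1 (0.305). Of 6981 genes 48 changed (20 higher, 28 lower; 25 without Con 3 and 29 without T2D 1). This unnamed cluster held 74 to 85 cells per Con library and 254 to 410 per T2D library. Whether the makeup of its cells differed between the groups was not examined, so its values may mix makeup with expression. In Cluster 16, Fos rose from 222 to 399 CPM (0.84, adjusted p = 0.00161). The B cell transcripts Bank1 (90.9 to 29.1 CPM, −1.60) and H2-Aa (411 to 203 CPM, −0.99) fell, among 18 changed of 6340 genes (9 higher, 9 lower; 10 without T2D 3).

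With all kept cells of a library summed, which mixes expression with the makeup of the blood, Cxcr3 rose from 17.3 to 38.1 CPM (1.14, adjusted p = 0.00235). Nr4a3 (31.8 to 12.8 CPM, −1.32, adjusted p = 0.00356) and Nfkbid (210 to 117 CPM, −0.85, adjusted p = 0.00364) fell. Ccl5 rose (1.24) and lost its call without Con 1, Con 2 or Con 3 (0.0997). Of 13645 genes 562 changed (307 higher, 255 lower), 27.9% without overlap against 10% by chance. The count was 187, 58 and 263 without Con 1, 2 and 3, 304 without T2D 2 and 158 without T2D 3.

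The third comparison tested 35 gene lists fixed before the data were examined, in each class. Interferon-stimulated genes rose in 10 of the 11 classes with enough members (adjusted p = 0.516 to 0.659 with an estimated correlation). In neutrophil-like cells the median log2 fold change of 35 members was 1.01 (adjusted p = 2.29e-17 with limma camera at a preset correlation, and adjusted p = 0.516 with an estimated correlation). There 12 rose and 0 fell (19 and 0 adjusted over the list alone). The antiviral genes Rsad2 (1.44), Rtp4 (1.23) and Oasl2 (1.08) rose with Ifit3b. In CD4 T-like cells 10 of 42 members rose (18 adjusted over the list alone; median 0.22), with Iigp1 (1.00), Slfn1 (0.46), Gbp4 (0.45) and Ifi209 (0.43). In B-like cells 9 of 47 rose (12; median 0.21), with Slfn1 (0.97) and Ifi209 (0.35). In CD8 T-like cells 6 of 44 rose (15; median 0.18), with Igtp (0.57). The interferon-led Cluster 12 was part of the B-like class, while the interferon-led Cluster 21, nearest to T cells by markers, was in no tested class. The list's median was 0.43 in regulatory T-like, 0.35 in non-classical and 0.23 in classical monocyte-like, 0.15 in NK-like cells, 0.26 in Cluster 10 and 0.21 in Cluster 16. The classical monocyte call was lost without T2D 1 (0.0511) and that of Cluster 16 without Con 2 or T2D 1 (0.0832). MHC class I genes rose in B-like (median 0.14), platelet-like (0.63), eosinophil-like (0.37) and both monocyte-like classes (0.19 each), with adjusted p = 0.516 to 0.784 with an estimated correlation. Their member H2-Q7 rose in B-like cells (0.45; lost without Con 2, 0.0732). Each of these 5 calls was lost without 1 or more libraries: T2D 1 in B-like (0.0704), Con 2 in platelet-like (0.172) and Con 2, T2D 1 or T2D 2 in eosinophil-like cells (0.0986). In monocyte-like cells it was Con 1 or T2D 1 in the non-classical (0.210) and Con 1, Con 2 or T2D 1 in the classical class (0.884).

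Of the 357 pairs of list and class tested, 94 passed with the preset correlation (46 higher, 48 lower), and between 72 and 101 did in the fits without 1 library. In the highest of the other splits of the libraries, which mix the groups, 54 passed. Passing with the preset correlation is thus not particular to the real split. None of the 94 held with an estimated correlation (lowest adjusted p = 0.516, 27 of all pairs at an unadjusted p under 0.05). limma's fry test, which asks whether a list's genes move one way on balance, called 0 after adjustment and 75 at an unadjusted p under 0.05.

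**Figure D4:**
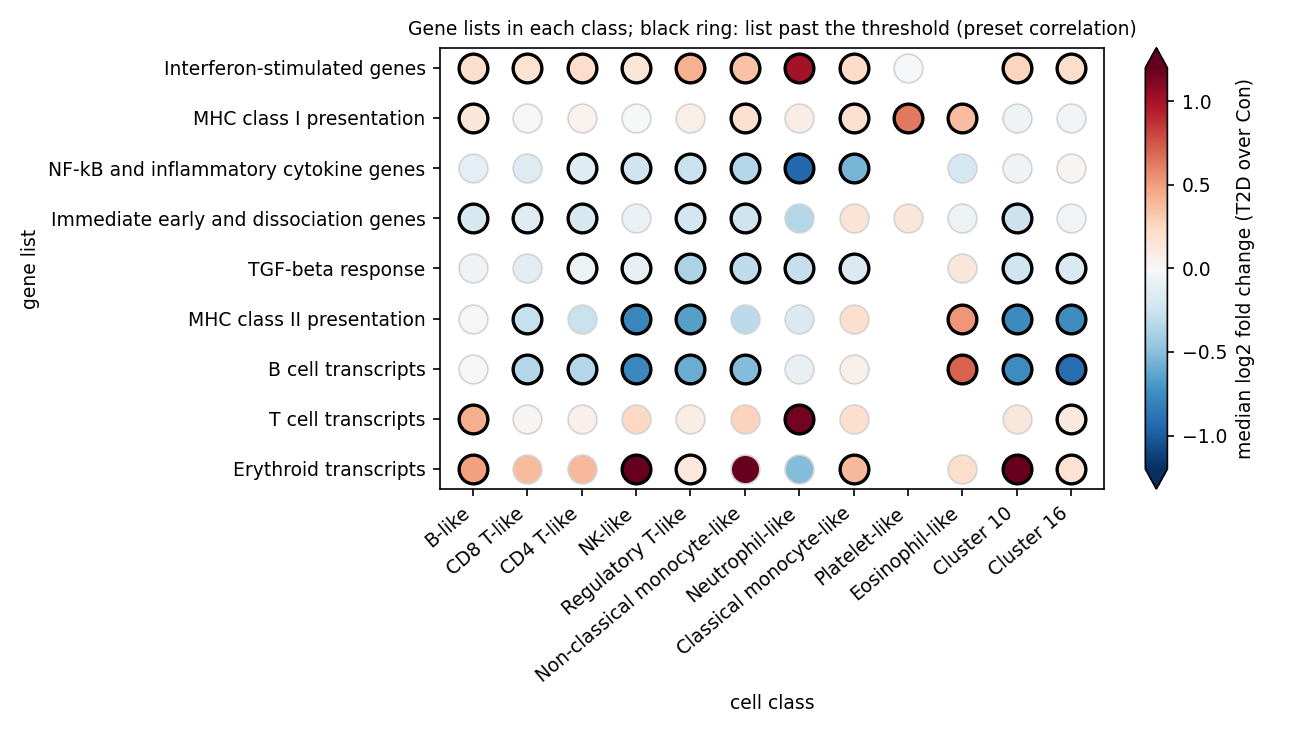
Median log2 fold change (T2D over Con, colour, clipped at ±1.2) of 9 gene lists (y axis) in 12 classes (x axis), with a black ring where the list passed with the preset correlation. Interferon-stimulated genes had medians of 1.01 in neutrophil-like and 0.22 in CD4 T-like cells, NF-kB genes −0.94 in neutrophil-like and −0.56 in classical monocyte-like cells, and B cell transcripts −0.77 in NK-like cells.

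Immediate early and dissociation-induced genes, the first to respond to stimulation or cell handling, fell in 6 of 12 classes (adjusted p = 0.516 to 0.736 with an estimated correlation). In CD4 T-like cells 12 of 31 members fell and 1 rose (15 and 2 adjusted over the list alone; adjusted p = 2.01e-06, and adjusted p = 0.583 with an estimated correlation), with Nr4a3 and Fosb lower and Rhob (0.46) higher. In CD8 T-like cells 7 fell and 1 rose (12 and 2), with Ier2 (−0.59). In B-like cells 5 of 32 fell (9), with Junb and Csrnp1 (−0.47). In regulatory T-like cells 5 of 28 fell (10), with Nr4a1 and the phosphatase gene Dusp2 (−0.97). In Cluster 10 Junb (−0.76), Zfp36 (−0.82) and Nr4a1 (−1.23) fell and Dusp5 (0.72) rose, among 4 lower and 2 higher (10 and 3). In non-classical monocyte-like cells 4 fell and 1 rose (7 and 3), with Csrnp1 (−1.13, lost without Con 1 at 0.0564). The list's call was lost without Con 1 or Con 3 in Cluster 10 (0.684) and without Con 1 or Con 2 in non-classical cells (0.0700).

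NF-kB and inflammatory cytokine genes fell in 6 of 11 classes (adjusted p = 0.516 to 0.628 with an estimated correlation). In neutrophil-like cells 14 of 30 members fell and 0 rose (19 and 0 adjusted over the list alone), with a median of −0.94 (adjusted p = 5.77e-15, and adjusted p = 0.516 with an estimated correlation). Among them were Nfkbia (−1.60), an inhibitor of NF-kB, Nfkbiz (−1.5) and Nfkbid (−1.30), nuclear regulators of its targets, and the receptor gene Ccrl2 (−1.01). In classical monocyte-like cells 3 of 35 fell and 1 rose (10 and 3; median −0.56), with Rel and Sod2 (−1.06) lower and Ccl2 higher. In non-classical cells 3 of 33 fell (9 lower and 1 higher over the list alone; median −0.35), with Rel (−0.93) and Cd83 (−1.03). These 2 classes had adjusted p = 0.573 and 0.628 with an estimated correlation. The list also passed lower in NK-like (median −0.24, with Nfkbia at −0.71), regulatory T-like (−0.27) and CD4 T-like cells (−0.15), with adjusted p = 0.516 to 0.521 with an estimated correlation. Those 3 calls were lost without Con 1 in NK-like (0.115), T2D 3 in regulatory T-like (0.0746) and Con 1 or T2D 3 in CD4 T-like cells (0.215). TGF-beta response genes passed lower in 8 classes (adjusted p = 0.516 to 0.623 with an estimated correlation), among them non-classical monocyte-like cells (median −0.31, 3 lower, 6 adjusted over the list alone, adjusted p = 1.76e-05). In CD4 T-like cells 6 of 16 fell (6), with Smad7 (−0.78), Tgif1 (−0.68), Junb (−0.52) and Rgs1 (−0.47), and in neutrophil-like cells 4 fell (5), with Tgif1 (−1.60), Bhlhe40 (−1.27) and Skil (−0.97). Junb also belongs to the immediate early list, so the falls of both lists are not independent. All but the non-classical call of the TGF-beta list were lost in 1 or more fits. Among lymphocytes this was without Con 1, T2D 1 or T2D 3 in CD4 T-like (0.136), Con 2 or Con 3 in NK-like (0.293) and Con 2 in regulatory T-like cells (0.0723). It was any library but T2D 2 in neutrophil-like (0.309) and T2D 1 in classical monocyte-like cells (0.0535). In Cluster 10 it was Con 1 or Con 2 (0.0986) and in Cluster 16 any library but T2D 1 (0.220).

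Transcripts of other cell types moved with the groups. B cell transcripts fell in NK-like cells (5 of 12 lower, 8 adjusted over the list alone; median −0.77, adjusted p = 2.33e-11, and adjusted p = 0.516 with an estimated correlation), with Ighm and Ighd (−0.83). With doublets kept, Ighd was at 0.0519 there (adjusted p = 0.980). The list also fell in Cluster 10 (median −0.76), Cluster 16 (−0.91), regulatory T-like (−0.59), non-classical monocyte-like (−0.52), CD8 T-like (−0.35) and CD4 T-like cells (−0.35) and rose in eosinophil-like cells (0.71). In all 8 classes they had adjusted p = 0.516 to 0.714 with an estimated correlation. Counted as B transcript UMIs per cell, the log2 change was 0.03 ± 0.19 (SE) in CD4 T-like and −0.10 ± 0.21 in CD8 T-like cells. It was −0.17 ± 0.15 in non-classical monocyte-like and −0.41 ± 0.28 in regulatory T-like cells. NK-like cells had −0.66 ± 0.10, Cluster 10 −0.42 ± 0.06 and Cluster 16 −0.73 ± 0.15. MHC class II genes, which B and antigen-presenting cells express, fell in NK-like cells (5 of 8 lower, 6 adjusted over the list alone; median −0.78, with Cd74 at −0.69; adjusted p = 0.516 with an estimated correlation). They also fell in Cluster 10 (−0.76), Cluster 16 (−0.76), regulatory T-like (−0.67) and CD8 T-like cells (−0.28) and rose in eosinophil-like cells (0.53). These 6 classes had adjusted p = 0.516 to 0.770 with an estimated correlation. In CD8 T-like cells the first list lost its call without Con 1 (0.0698) and the second without Con 1, Con 3 or T2D 3 (0.294). In CD4 T-like cells the first list lost it without Con 1, Con 3 or T2D 3 (0.267), and in regulatory T-like cells without Con 1 (0.179). In B-like cells 4 of 12 T cell transcripts rose (10 adjusted over the list alone; median 0.43; adjusted p = 0.516 with an estimated correlation), with Cd8a at 0.72 (lost without Con 2, 0.0937). So did 4 of 24 cytotoxic genes (10; median 0.44; adjusted p = 0.516 with an estimated correlation), with Nkg7 at 0.96 (lost without T2D 3, 0.0597). T cell transcripts also rose in neutrophil-like cells (median 1.16, with Cd3e at 2.17; adjusted p = 0.516 with an estimated correlation). They also rose in Cluster 16 (0.11; 0.516 with an estimated correlation), where the call was lost without any library but Con 3 (0.191). Erythroid transcripts rose in B-like (median 0.49), NK-like (2.28), classical monocyte-like (0.39) and regulatory T-like cells (0.13) and in Clusters 10 (1.41) and 16 (0.18, with Hbb-bs at 1.70), with adjusted p = 0.516 to 0.659 with an estimated correlation. The regulatory T-like and Cluster 10 calls were lost without Con 1 or T2D 3, without Con 3 in the former (0.173) and without T2D 2 in the latter (0.139).

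In the myeloid classes, granule and alarmin genes rose in neutrophil-like cells (7 of 28 higher, 1 lower; 9 and 1 adjusted over the list alone), with the collagenase gene Mmp8 (1.00) and Ifitm6 (1.03). Their median was 0.21 (adjusted p = 0.00257, and adjusted p = 0.623 with an estimated correlation). Unfolded protein response genes rose in classical monocyte-like cells (1 of 25, 4 higher and 1 lower over the list alone; median 0.21; adjusted p = 0.516 with an estimated correlation), with the heat shock gene Hsph1 (1.08, lost without any library but T2D 1, 0.304). Monocyte transcripts rose in the classical (0.26) and non-classical class (0.47). Both had adjusted p = 0.516 with an estimated correlation. In non-classical cells neutrophil transcripts rose (1.61; lost without Con 3, 0.0690) and B cell activation genes fell (−0.21, with Cd83), with adjusted p = 0.623 and 0.516 with an estimated correlation. Proliferation genes rose in classical cells (0.27; lost without Con 2 or T2D 1, 0.118; adjusted p = 0.516 with an estimated correlation). Targets of p53 fell in neutrophil-like (−0.16; lost without Con 3, 0.125), classical monocyte-like (−0.18; lost without any library but T2D 2, 0.145) and eosinophil-like cells (−0.69; lost without any library but T2D 3, 0.442). They had adjusted p = 0.516 in each class with an estimated correlation. Platelet transcripts rose in neutrophil-like cells (0.73; lost without Con 1, Con 2, T2D 1 or T2D 2, 0.248; adjusted p = 0.736 with an estimated correlation). Naive T cell and homing genes rose there too (0.28; lost without Con 1, Con 2, T2D 1 or T2D 3, 0.220), with Klf2 (0.67), in the class where T cell transcripts rose (1.16, with Cd3e at 2.17). The homing list had adjusted p = 0.516 with an estimated correlation. The latter list also rose in eosinophil-like cells (0.16; lost without T2D 1 or T2D 2, 0.109; 0.601 with an estimated correlation).

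Among lymphocytes, chemokine receptor and adhesion genes rose in Cluster 10 (4 of 25, 7 higher and 1 lower over the list alone; median 0.25), a call lost without Con 3 (0.0534) and with an estimated correlation (adjusted p = 0.516). Its members Itgb1 (0.52) and Ccr2, a chemokine receptor of monocytes and effector T cells (0.60), rose. Itgb1 lost its call without Con 1, Con 3, T2D 1 or T2D 2 (0.288) and Ccr2 without any library but T2D 3 (0.315). The list also rose in B-like cells (0.08; lost without any library but Con 1, 0.236; adjusted p = 0.665 with an estimated correlation). In B-like cells T cell activation and checkpoint genes (6 higher and 2 lower of 32; median 0.24, with Ctla4 at 1.37) and B cell activation genes (2 higher and 1 lower of 33; median 0.08) rose, in the class where T cell transcripts (median 0.43) and cytotoxic genes (0.44) rose too. Both activation lists lost their call without Con 2 or T2D 2 (0.554 and 0.412), with adjusted p = 0.686 and 0.641 with an estimated correlation. Oxidative phosphorylation genes rose in Cluster 10 (0.17 over 71 members, none past the threshold alone; adjusted p = 0.665 with an estimated correlation). Fatty acid uptake and oxidation genes rose in Cluster 16 (0.16; lost without Con 1, Con 2, Con 3 or T2D 3, 0.273; adjusted p = 0.516 with an estimated correlation). Ribosomal protein genes fell in CD4 T-like (−0.13), regulatory T-like (−0.19), NK-like (−0.17), B-like (−0.09), CD8 T-like (−0.08) and classical monocyte-like cells (−0.06) and rose in eosinophil-like (0.27) and platelet-like cells (0.33). They had adjusted p = 0.600 to 0.874 with an estimated correlation. Mitochondrially encoded genes fell in CD4 T-like (−0.29), NK-like (−0.24), regulatory T-like (−0.23), CD8 T-like (−0.22), non-classical monocyte-like (−0.20) and B-like cells (−0.14) and rose in eosinophil-like (0.70) and neutrophil-like cells (0.46). They had adjusted p = 0.516 to 0.714 with an estimated correlation. The ribosomal call was lost in B-like (without T2D 3, 0.185), CD8 T-like (Con 1 or T2D 3, 0.112), classical monocyte-like (Con 1, Con 2, T2D 1 or T2D 3, 0.608) and platelet-like cells (Con 2 or T2D 3, 0.865). The mitochondrial call was lost in B-like (Con 1, Con 3 or T2D 3, 0.508), NK-like and regulatory T-like (Con 1, Con 2, Con 3 or T2D 3, 0.305 and 0.308), non-classical monocyte-like (Con 2 or T2D 3, 0.172) and neutrophil-like cells (Con 2 or T2D 1, 0.0790). Lists for glucocorticoid response, glycolysis, cholesterol synthesis, inflammasome, Toll-like receptors, NRF2, insulin and PI3K signalling, and complement and Fc receptors passed in 0 of the 10 to 12 classes tested for each (limma camera; lowest adjusted p 0.0563, for Toll-like receptors). At an unadjusted p under 0.05, cholesterol synthesis was at 3 classes, Toll-like receptors at 2, and glycolysis and the glucocorticoid response at 1 each. Endothelial and hepatocyte lists had too few measured members.

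The fourth comparison asked whether the T2D effect differed between B-like, CD8 T-like, CD4 T-like and NK-like cells, the 4 classes with the most cells among those tested for gene changes, by an interaction term over 11176 genes with the library as a block. The effect differed between CD4 T-like and B-like cells for 91 genes, between CD8 T-like and B-like for 63, and NK-like and B-like for 52. It differed between NK-like and CD4 T-like for 26, NK-like and CD8 T-like for 11, and CD4 and CD8 T-like cells for 2. Myc, a driver of growth and biosynthesis, had a log2 fold change of 0.83 in CD8 T-like and −0.43 in B-like cells (difference 1.25, adjusted p = 6.22e-18), and Nfkbiz 0.39 and −0.31. The log2 fold change of H1f2 exceeded that in B-like cells by 1.33 in NK-like and by 0.66 in CD4 T-like cells, and that of Tcf7 was −0.88 in NK-like and 0.55 in B-like cells. In B-like cells, where T cell transcripts rose as a list, Tcf7 lost its call without Con 1, Con 2 or T2D 3 (0.101). S1pr1, the receptor for lymphocyte egress, had 0.05 in CD4 T-like and 0.57 in B-like cells, and Midn, a factor in the turnover of immediate early proteins, −0.85 in CD4 and −0.19 in CD8 T-like cells. For CD4 T-like against B-like cells, the count was 54, 53, 52 and 33 without Con 1, Con 2, T2D 2 and T2D 3. It was 36 without T2D 3 for CD8 against B, and 34 and 29 without Con 2 and T2D 3 for NK against B. Against CD4 T-like cells, NK-like cells had 12, 11, 13 and 13 without Con 1, Con 2, T2D 1 and T2D 3. There were 5 and 7 without Con 2 and T2D 2 for NK against CD8, and 1 to 4 for CD4 against CD8 without every library but Con 2.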

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

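The tests of blood handling, of the called members of both lists within B-like clusters, and of all pairs of classes for interferon-stimulated genes, and the setting of both free RNA values beside the other splits of the libraries and with errors within libraries, were chosen only after the result was seen. The other tests here were chosen before.

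The T2D effect differed between B-like cells and each of CD4 T-like, CD8 T-like and NK-like cells by the interaction test over 11176 genes (edgeR quasi-likelihood, Benjamini-Hochberg). Against B-like cells, 91 genes had a different effect in CD4 T-like cells (22 higher and 69 lower there), 63 in CD8 T-like cells (17 and 46) and 52 in NK-like cells (25 and 27). Between NK-like and CD4 T-like cells 26 genes differed (18 and 8), between NK-like and CD8 T-like cells 11 (8 and 3), and between CD4 and CD8 T-like cells 2, Midn (−0.85 and −0.19) and Klrd1 (0.69 and 0.07). Genes with log2 fold changes of opposite sign were Myc (0.83 in CD8 T-like, −0.43 in B-like), Myb (0.73 and −0.23), Ddit4, a stress-induced brake on mTORC1 (0.69 in NK-like, −0.54 in B-like), and Ets2 (−0.29 in CD4 T-like, 0.69 in B-like). The interaction test shows that these effects differ, not that the gene changed in each class. Ddit4 lost its call in NK-like cells without Con 1, Con 2, T2D 1 or T2D 2 (highest adjusted p 0.222). Slfn1, an interferon-induced gene, had a log2 fold change of 0.31 in CD8 T-like against 0.97 in B-like cells, and Zfp36l2, an RNA-decay factor, −0.13 in NK-like against −0.61 in CD4 T-like cells. Slfn1 lost its call in CD8 T-like cells without Con 2 or T2D 3 (0.184), and Zfp36l2 in CD4 T-like cells without T2D 3 (0.0980). The B-like class held the interferon-led Cluster 12. The interferon-led Cluster 21, with its best marker scores for CD4 and CD8 T cells (1.27 and 1.22), was in neither T-like class. Whether this bears on the Slfn1 difference was not tested. Some differences involve transcripts of another cell type, such as Nkg7 (0.02 in CD8 T-like, 0.96 in B-like) and Ighm (−0.90 in NK-like, 0.08 in B-like). The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave the counts above and the highest other split gave 3, 2, 2, 0, 1 and 0, for CD4, CD8 and NK against B, NK against CD4, NK against CD8 and CD4 against CD8.

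Immediate early genes passed lower in T2D in 6 of 12 classes and NF-kB genes in 6 of 11 with the preset correlation, and neither did in any class with an estimated correlation (adjusted p = 0.516 to 0.736 and 0.516 to 0.628). A smaller share of Cluster 0, the B cell state with Cd83 among its leading genes, could bear only on the B-like class. For that class it is argued against, because the 93 genes called lower in B-like cells had a median log2 fold change of −0.41 in the class, −0.40 within Cluster 0 (over the 90 of them tested there) and −0.38 within Cluster 1 (over 92), the smaller being 93.55% of the class median (the 7 called members of both lists gave −0.43, −0.42 and −0.40). States within the other classes were not examined. A difference in how the blood of the groups was handled may account for the pattern and cannot be told apart from the diabetic state, because each group's handling goes with the group. It would lower these genes in most classes, and 8 of 12 tested classes had more called members lower than higher, such as neutrophil-like (21 lower, 2 higher) and CD4 T-like cells (13 and 2), while classical monocyte-like cells (5 lower, 6 higher) and Cluster 16 (0 and 2) had more higher. The diabetic state stays open as a biological explanation, as do streptozotocin itself and any difference in diet. All of these go with the group, cannot be told apart and were not tested separately.

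B cell transcripts passed lower in NK-like cells and 6 other non-B classes of T2D with the preset correlation, and in none with an estimated correlation (adjusted p = 0.516 to 0.714). Free RNA from B cells in equal amounts cannot be told apart: B transcript UMIs per cell changed by 0.03 ± 0.19 (SE) on the log2 scale in CD4 T-like and −0.66 ± 0.10 in NK-like cells, by 3.14 standard errors the largest difference of 21 pairs of classes (2.23 in the highest other split of the libraries). That is over the bound of 3 set beforehand, but the bound took the classes as independent, and with errors on differences within libraries the pair gave 3.58 and another split 6.23. Undetected doublets with B cells are a candidate explanation. For this, the 63 of 1199 NK-like cells with at least 10% of the B transcript UMIs of a median B-like cell were left out. The median change of the list then went from −0.77 to −0.29, 37.97% of its size. The second median covers 9 members, fewer than were tested in all NK-like cells, so the medians are not over the same genes. B transcript UMIs per NK-like cell below the limit were 3.508 ± 0.96 (SD, n = 3) in Con and 3.35 ± 0.24 in T2D. However, a limit on the transcript itself shrinks the change partly by construction. The share of NK-like cells over the limit was 7.14% ± 2.06 (SD, n = 3) in Con and 4.48% ± 2.15 in T2D, with overlap between the groups, Ighd (0.0519) and Igkc (0.288) turned positive in NK-like cells with doublets kept, and a true change within NK-like cells stays open.

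Interferon-stimulated genes passed higher in T2D in 10 of 11 classes with the preset correlation, and in 0 with an estimated correlation (adjusted p = 0.516 to 0.659) or with fry. A larger interferon-led B cell state (Cluster 12) is argued against, because the median in B-like cells was 0.21 in the class and 0.30 without Cluster 12, 138.5% of it. Free RNA from one source in equal amounts cannot be told apart: the highest gain in UMIs per cell, 10.2 ± 4.98 (SE) in neutrophil-like cells, differed from the lowest, 1.02 ± 0.40 in NK-like cells, by 1.84 standard errors. Cluster 10 (3.43 ± 0.40) differed from NK-like cells by 4.28, the largest of 45 pairs (2.33 in the highest other split), but with errors within libraries the pair gave 4.59 and another split 5.24, so that test does not set the real split apart. A response to interferon in the T2D mice stays open and was not tested separately. Diabetes, streptozotocin itself and any difference in diet cannot be told apart as its source.

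For the other counts the 10 splits are also too few for a share under 0.05. The real split and the highest other gave 193 and 2 genes in B-like, 173 and 5 in CD8 T-like, 246 and 4 in CD4 T-like, 42 and 1 in NK-like, 19 and 2 in regulatory T-like, 60 and 2 in non-classical and 70 and 1 in classical monocyte-like cells. They gave 188 and 2 in neutrophil-like, 16 and 1 in eosinophil-like, 1 and 1 in platelet-like cells (2 splits as large), 48 and 5 in Cluster 10, 18 and 1 in Cluster 16 and 562 and 15 in all cells summed. For gene lists it was 94 and 54, and for shares 6 and 0.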

How the results depend on the processing

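The clustering without leading genes was chosen only after the result was seen, and all other alternatives before the data were examined. Over these other alternatives, 114 counts stayed within 1.5 times and 35 moved. Of the single genes, 4660 values kept direction and side of the threshold, 305 no longer passed, 138 newly passed and 8 reversed, with 112, 7, 4 and 6 for shares and 185 and 191 kept and lost for lists. With 1 library left out, 66 counts were within 1.5 times and 60 moved, genes gave 2433, 532, 68 and 1, shares 103, 12, 2 and 9, and lists 442 and 121. Median-of-ratios size factors moved no count by 1.5 times. Unless a cause is given, the cause was not tested. Eosinophil-like and Cluster 16 sums rest on few cells, and drawing equal cell numbers, which leaves fewer UMIs, lowered their counts to 0 and 2.

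Counts of changed genes that moved were as follows. DESeq2 called 112 in CD8 T-like, 143 in CD4 T-like, 26 in NK-like, 113 in neutrophil-like cells, 11 in Cluster 16 and 923 in all cells summed, and limma-voom 11 in Cluster 16. Without the filter on low counts, where more genes are tested, there were 502 in B-like, 276 in CD8 T-like, 40 in regulatory T-like, 115 in non-classical and 145 in classical monocyte-like cells and 939 in all cells. The stricter filter gave 2 in platelet-like cells. Equal cell numbers gave 162 in CD4 T-like, 24 in NK-like, 7 in regulatory T-like, 34 in non-classical monocyte-like, 82 in neutrophil-like, 0 in platelet-like and 0 in eosinophil-like cells, 23 in Cluster 10 and 2 in Cluster 16. With doublets kept, NK-like cells had 19 and eosinophil-like cells 6, and resolution 2 gave 3 in regulatory T-like cells. An estimated correlation and fry called 0 lists each.

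With the replicate block, that is the library number as a block, the counts were 575 in B-like, 282 in CD8 T-like, 53 in regulatory T-like, 95 in non-classical monocyte-like and 1 in eosinophil-like cells, and the shares of Cluster 8 (0.70, adjusted p = 0.0867) and NK-like cells (0.75, 0.0810) no longer passed, while that of eosinophil-like cells (−1.07, 0.0485) newly did. It moved no other count by 1.5 times and ended no other call of a share, and of the 94 list calls 91 were among the 101 it made. Whether the numbers pair the libraries cannot be told from 3 libraries per group. After each group's mean log2 CPM was subtracted per gene, the deviations of same-numbered libraries correlated at −0.24 to 0.41 in all cells summed. By that correlation, every Con library was closest to its own number only in regulatory T-like and platelet-like cells.

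For shares (log2 fold change), TMM over class counts moved B-like (−0.65, adjusted p = 0.0359) and eosinophil-like cells (−1.47, adjusted p = 0.0359) past the threshold and Cluster 8 (0.40) and NK-like cells (0.46) out of it. It reversed values that had not passed: CD4 T-like −0.0941, CD8 T-like −0.0553, Cluster 17 −0.112, Cluster 20 −0.0781 and non-classical monocyte-like −0.13. limma on log2 odds gave Cluster 8 0.72 and NK-like 0.77, both with adjusted p = 0.0533. Named leukocytes as denominator left 3 shares past the threshold, which include no numbered cluster by construction, and doublets kept left 3. Clusters were numbered only in the main clustering. Doublets kept, the stricter filters on cells and resolutions 0.5 and 2 therefore gave neither shares nor changed genes for the numbered clusters. With doublets kept the gamma-delta T-like share was 0.75 (adjusted p = 0.0618), because the class then also held another cluster, led by Trdc and Trgc2. At resolution 0.5 the eosinophil-like share newly passed (−1.14, adjusted p = 0.0495). Stricter filters on cells reversed platelet-like cells (0.0266). Made again without leading genes, Cluster 10 (1.96), Cluster 22 (1.84), regulatory T-like (1.803), NK-like (0.77) and Cluster 8 (0.69) stayed past the threshold, and the gamma-delta T-like class had no match, so it gave no value.

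Genes that reversed, none past the threshold then, were Ighd (0.0519) and Igkc (0.288) in NK-like and H2-Ab1 (−0.12) and Ighm (−0.00961) in eosinophil-like cells with doublets kept. With equal cell numbers they were S100a9 in non-classical monocyte-like (−0.14), H2-Ab1 (−0.12) and Tapbp (0.24) in eosinophil-like cells and Acaa2 in Cluster 16 (−0.19). S100a9 in non-classical monocyte-like cells also reversed without T2D 3 (−0.351), against 3.10 at the highest, without Con 1.

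Leaving out each library in turn, changed genes numbered 43 to 297 in B-like, 81 to 152 in CD8 T-like, 128 to 198 in CD4 T-like, 26 to 54 in NK-like, 4 to 38 in regulatory T-like, 14 to 99 in non-classical and 21 to 107 in classical monocyte-like, 73 to 214 in neutrophil-like, 0 to 2 in platelet-like and 1 to 22 in eosinophil-like cells, 25 to 64 in Cluster 10, 10 to 24 in Cluster 16 and 58 to 617 in all cells. The interaction counts were 33 to 129 for CD4 against B, 36 to 64 for CD8 against B, 29 to 46 for NK against B, 1 to 4 for CD4 against CD8, 5 to 13 for NK against CD8 and 11 to 28 for NK against CD4. Shares past the threshold numbered 3 to 6. Cluster 22 ranged from 1.35 to 1.78, Cluster 8 from 0.595 to 0.776 and NK-like cells from 0.670 to 0.932 (log2 fold change). Of shares that had not passed, some reversed without 1 library: classical monocyte-like cells ranged from −0.586 to 0.102 (also 0.0550 without Con 2 and 0.0448 without T2D 3), neutrophil-like from −0.574 to 0.200 (0.115 without T2D 1) and non-classical monocyte-like from −0.124 to 0.927. Conventional dendritic-like cells ranged from −0.168 to 0.939, Cluster 17 from −0.0462 to 0.516 and Cluster 20 from −0.0188 to 0.531.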

Other observations

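The genes described here were chosen after their values were seen, and no test beyond the class comparisons (edgeR quasi-likelihood, Benjamini-Hochberg) was run on them. A value given without a left-out library kept its call in each fit without 1 library.

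The linker histone genes H1f4 and H1f2 moved in more classes than the rule named. H1f4 had a positive log2 fold change in 9 of 9 classes where it was tested and rose in 5, among them CD4 T-like (1.39) and CD8 T-like cells (1.28). H1f2 was positive in 9 of 12 and rose in 4, among them NK-like (1.27) and classical monocyte-like cells (1.01). It also rose in CD4 T-like cells (0.65, lost without Con 1, Con 2, Con 3 or T2D 3, highest adjusted p 0.163) and non-classical monocyte-like cells (0.96, lost without any library but T2D 1, 0.200). Most histone messages lack a poly(A) tail, so a 3′ count of them covers only the tailed part. Cpt1a, of fatty acid import into mitochondria, was positive in 10 of 10 classes and rose in 3, B-like (0.58), CD8 T-like (0.45) and NK-like cells (0.58, lost without Con 2, Con 3, T2D 2 or T2D 3, 0.274). Slc25a20, the carnitine carrier of mitochondria, was positive in 10 of 10 and rose in B-like cells (0.51, lost without Con 2, 0.0669). The list of fatty acid uptake and oxidation genes passed in 1 of 10 classes, Cluster 16, a call lost without 1 or more libraries and with an estimated correlation (adjusted p = 0.516). It had adjusted p = 0.333 in B-like, 0.161 in CD8 T-like and 0.283 in NK-like cells (limma camera). Plin2, which coats lipid droplets, was positive in 7 of 7 and rose in neutrophil-like cells from 78.1 to 246 CPM (1.74) and in non-classical monocyte-like cells (0.78, lost without Con 1 or T2D 3, 0.0780).

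The circadian repressor gene Per1 was positive in 0 of 11 classes and fell in 4, among them CD4 T-like (−0.93), CD8 T-like (−0.62) and neutrophil-like cells (−0.77). Fkbp5, induced by glucocorticoids, was positive in 9 of 10 and rose in 3, with calls lost in all 3 without 1 or more libraries, while the list of glucocorticoid-responsive genes passed in 0 of 11 classes (limma camera; 1 at an unadjusted p under 0.05). Cdkn1a, a p53 target, was positive in 0 of 10 classes and fell in 3, B-like (−1.44), non-classical monocyte-like (−0.67) and neutrophil-like cells (−0.95, lost without Con 1, Con 2, T2D 2 or T2D 3, 0.473). Bbc3, a pro-apoptotic p53 target, was positive in 0 of 10 and fell in 4, among them CD4 T-like (−0.73) and CD8 T-like cells (−0.64). The list of p53 targets had adjusted p = 0.416 in B-like, 0.218 in CD4 T-like, 0.947 in CD8 T-like and 0.792 in non-classical monocyte-like cells (limma camera). It passed lower in 3 of 11 classes, neutrophil-like, classical monocyte-like and eosinophil-like cells, each lost without 1 or more libraries and with an estimated correlation (adjusted p = 0.516). The time of day at which the blood was drawn is not given in the sources used here.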
